A study of Mus musculus with 15 samples.

How the data were processed

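Gene expression was measured in RAW264.7 cells, a mouse macrophage-like line, on 15 Affymetrix arrays, with 1 biotin-labelled RNA sample on each array. Per the labels, cells grew in alpha-MEM with serum, and the medium given on days 0 and 3 was serum-free and held RANKL or no RANKL. The arrays fall into 9 groups by treatment and day of culture, with 1 or 2 arrays in each. RANKL at day 3 was not analysed here. The labels do not say whether replicates are separate cultures, so the p-values may measure technical spread only.

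The deposited values are probe set signals in linear intensity units, which the authors made with MAS5, whose version is not given here. The authors had scaled the arrays, since the 2% trimmed mean of the signals was 500 on each of the 15 arrays. No further normalization was applied. The table holds 12488 probe sets. The 66 control probe sets of the manufacturer were left out of the tests; those of beta-actin and Gapdh served as a measure of RNA quality, and those of beta-actin were also set beside the Actb change. The other 12422 were tested with no filter on dim signals, as log2(signal + 32). The annotation lists 1 gene for 10833 probe sets, several genes for 396 and none for 1193. Probe sets of the last 2 kinds were tested and not named. Each of the 8251 genes is represented by its probe set with the highest mean log2 signal over all arrays. Where another probe set of a named gene had the opposite sign, the text says so for the genes with the largest changes.

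A linear model with 1 mean for each of the 9 groups was fitted to all arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend). It left 6 residual degrees of freedom, to which the empirical Bayes step added 5.39 prior degrees of freedom. The 3 groups with 1 array are assumed to vary like the others. Tests were two-sided, p-values were adjusted over all probe sets with the Benjamini-Hochberg method within each comparison, and the threshold was 0.05. The 8 comparisons were the RANKL effect (RANKL minus control of the same day) averaged over days 1, 2, 4 and 5, the RANKL effect at each of these days, the late minus early RANKL effect (mean of days 4 and 5 minus mean of days 1 and 2), and culture time (mean of days 4 and 5 minus mean of days 1 and 2) within RANKL cells and within control cells. Changes are log2 differences with the standard error from limma.

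The comparisons, the lists, the rule for naming genes and a first set of alternatives were fixed before the data were examined. The rule names, for the RANKL effect over the 4 days, the 10 largest rises and the 10 largest falls among genes past the threshold that changed the same way on each day. It names the 5 largest rises and falls past the threshold for every other comparison, and up to 4 members of each gene list by size of change. It also names a panel of 17 osteoclast and macrophage genes, of which 12 are represented (Acp5, Ctsk, Mmp9, Calcr, Nfatc1, Itgb3, Tnfrsf11a, Fos, Irf8, Csf1r, Mki67 and Tnf).

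The 29 gene lists cover osteoclast resorption, cell fusion, osteoclast transcription factors, negative regulators of osteoclast formation, RANK and NF-kB signalling, V-ATPase (the proton pump), lysosome, podosome and cytoskeleton, cell cycle, cyclin-dependent kinase inhibitors, oxidative phosphorylation, the TCA cycle, glycolysis, sterol biosynthesis, interferon response, macrophage markers, inflammatory mediators, dendritic cell markers, unfolded-protein and integrated stress response, oxidative stress response, hypoxia response, iron uptake and haem, ribosomal proteins, reference genes, and markers of stromal and osteoblast, T, B, neutrophil and erythroid cells. They hold 675 genes, of which 547 are represented. The list named cyclin-dependent kinase inhibitors also holds Rb1, Rbl1, Rbl2, Btg1, Btg2, Gadd45a and Gadd45b, which are not such inhibitors. Each list was tested with limma's camera against the other genes, two-sided, with a preset correlation of 0.01 and adjustment over the 29 lists within each comparison. Camera with an estimated correlation between genes was the alternative. Of the 232 list tests, the median, the mean and the test differed in sign in 49, of which 0 were past the threshold.

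The alternatives were pseudocounts of 1 and 100, quantile normalization, the upper 50% of probe sets by mean signal, no intensity trend, the replicate number as a block, each array left out in turn, and other definitions of a comparison. Added after the data were seen were fits without the day 1 pair, the beta-actin 3' to 5' signal ratio as a covariate, comparisons of adjacent days, a choice of probe sets on the arrays of days 3 to 5 alone, and the day 1 RANKL effect minus the mean effect of days 2, 4 and 5. No pairing of arrays by replicate number was seen, though weak pairing is not excluded. Over 15 pairs of groups, the correlation across probe sets of the replicate 1 minus replicate 2 differences ran from -0.17 to 0.12.

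The procedure was tested on simulated data with the same groups and 12422 probe sets, of which 200 changed. At a log2 change of 1, the RANKL effect over the 4 days recovered 93% of changed probe sets, single days between 13% (day 1) and 48% (day 4), and the late minus early effect 15%. At a log2 change of 2, the shares were 100%, 75% to 98% and 89%. False calls were 2.03% of the calls for the RANKL effect over the 4 days and up to 8.46% at day 5. They were 7.30% for culture time in RANKL cells and 5.48% at day 2. The simulated noise was normal and independent between probe sets and between arrays, unlike real arrays. For arrays, the number of arrays limits the precision. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.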

Results

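RNA of RAW264.7 cells was measured on 15 arrays after culture with or without RANKL, the cytokine that binds the receptor RANK and turns macrophage precursors into osteoclasts, the cells that resorb bone. Control cells gave 1 array at day 1, 2 at day 2, 2 at day 3, 2 at day 4 and 1 at day 5. RANKL cells gave 1 array at day 1 and 2 at each of days 2, 4 and 5. The labels call the RANKL cells mononuclear at days 1 and 2 and multi-nuclear at days 4 and 5. Values are MAS5 signals with a trimmed mean of 500 on each array. The median signal ran from 103 to 149 over the arrays, and between 50.4% and 56.2% of probe sets had a signal over 100. Replicate arrays correlated at r = 0.975 to 0.984 across probe sets, which are not independent replicates. The beta-actin 3' to 5' ratio, a sign of RNA quality, ran from 1.01 to 1.39.

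The arrays separated by day of culture and then by treatment. The first principal component held 35.8% of the variance and placed the 6 arrays of days 1 and 2 between -44.2 and -17.5. All later arrays lay between 12.8 and 32.8, except RANKL day 5 replicate 2 at -10.6. On the second component (13.7%), the 6 RANKL arrays of days 2, 4 and 5 lay between 1.62 and 32.1 and the 8 control arrays between -18.1 and 0.22. The RANKL day 1 array lay at -21.5, below every control array.

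**Figure D1:**
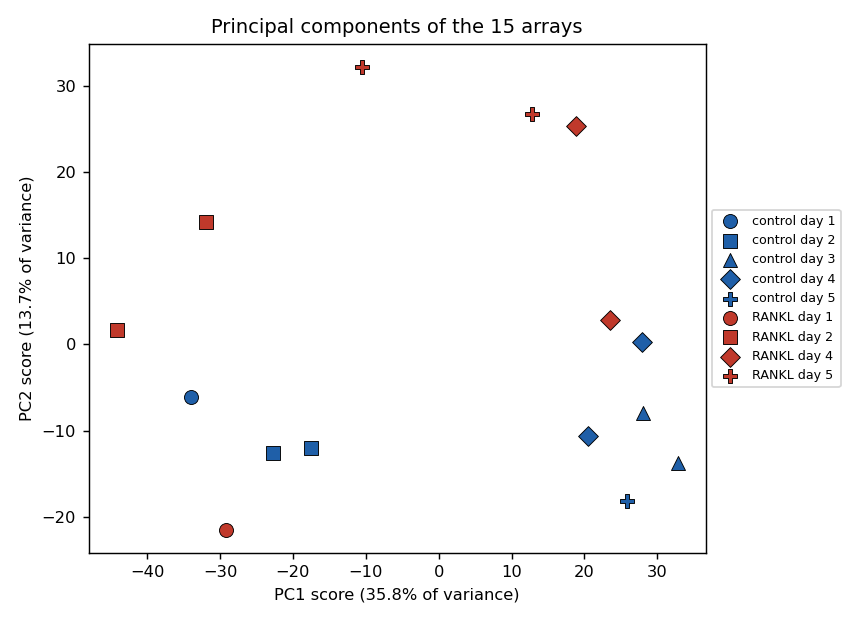
Scores of the 15 arrays on the first and second principal components, in log2 units, with 1 point for each array, colour for treatment and shape for day. Arrays of days 1 and 2 lie at or below -17.5 on the first axis, and RANKL arrays of days 2, 4 and 5 lie at or above 1.62 on the second.

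The RANKL effect over days 1, 2, 4 and 5 answers which genes differ between cells cultured for the same time with and without RANKL. Osteoclast genes such as Acp5 and Ctsk were higher with RANKL, and some interferon-induced genes and macrophage markers were lower. Acp5 (98859_at), which encodes the osteoclast enzyme tartrate-resistant acid phosphatase, was higher by 4.33 ± 0.21 (adjusted p = 1.58e-06; 3.39 to 6.06 over the alternatives). Ctsk (160406_at), cathepsin K, which degrades bone collagen, rose by 2.57 ± 0.15 (adjusted p = 7.19e-06; 1.70 to 3.62 over the alternatives). Nfatc1 (102209_at), the transcription factor that drives osteoclast formation, was higher by 2.09 ± 0.22 (adjusted p = 0.000958, 1.60 to 2.78 over the alternatives). Rises and falls with RANKL are differences from control cells of the same day, so they can also come from a change in control cells. In control cells the Nfatc1 signal was 4410 at day 1 and at most 2134 on later arrays. The Nfatc1 change with culture time in RANKL cells did not pass. Usp18 (95024_at), an interferon-induced protease, was lower (-1.68 ± 0.31, adjusted p = 0.0262; lost in 10 of 25 alternatives). Fcgr1 (102879_s_at), the high-affinity IgG receptor of macrophages, was lower (-1.77 ± 0.34, adjusted p = 0.0318; lost in 12 of 25). On all 6 RANKL arrays of days 2, 4 and 5 the signals of Acp5, Ctsk and Nfatc1 were above each of the 5 control arrays of those days. Usp18 was below them on all 6 and Fcgr1 on 5.

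In all, 136 of 12422 probe sets passed the threshold, 69 higher and 67 lower, and they represent 61 and 51 genes. Acp5, Ctsk and Mmp9 (2.24 ± 0.30, a gelatinase) belong to the panel fixed beforehand and had negative day 1 changes. The day 1 direction rests on 1 array against 1, where no probe set passed, so 1 direction on all 4 days does not show a response at day 1. The other largest rises with 1 direction on all 4 days were those of Ank, a pyrophosphate transporter (1.53 ± 0.11), Slc9b2 (1.46 ± 0.25), Clec4a2 (1.41 ± 0.20), Dock5 (1.38 ± 0.16) and Itgav, the integrin alpha v chain (1.33 ± 0.14). Slc6a8, Ak1, Mst1r and Plxnd1 rose by 1.15 to 1.24, and the other probe set of Slc6a8 had the opposite sign. The other largest falls were those of Ifi47 (-1.66 ± 0.25), Isg20 (-1.65 ± 0.30), Ms4a6c, Ambp, Evl, Sqor, Isg15 and Slfn4, from -1.62 for Ms4a6c to -1.33 for Slfn4, and the other probe set of Sqor had the opposite sign. Of the 6 RANKL arrays of days 2, 4 and 5, Sqor and Slfn4 were below the 5 control arrays of those days on 3. Slc6a8 and Plxnd1 were above them on 4. The rest of the 10 largest rises and 10 largest falls lay beyond them on 5 or 6. In the panel, Fos rose by 0.68 (adjusted p = 0.047, its other probe set having the opposite sign; lost in 18 of 25 alternatives) and Irf8, a transcription factor that restrains osteoclast formation, fell by 1.25 (adjusted p = 0.0255; lost in 11 of 25). The RANK gene Tnfrsf11a (0.51), Calcr (0.02), Itgb3 (0.04), Csf1r (-0.10), Mki67 (-0.30) and Tnf (-1.15) did not pass the test.

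**Figure D2:**
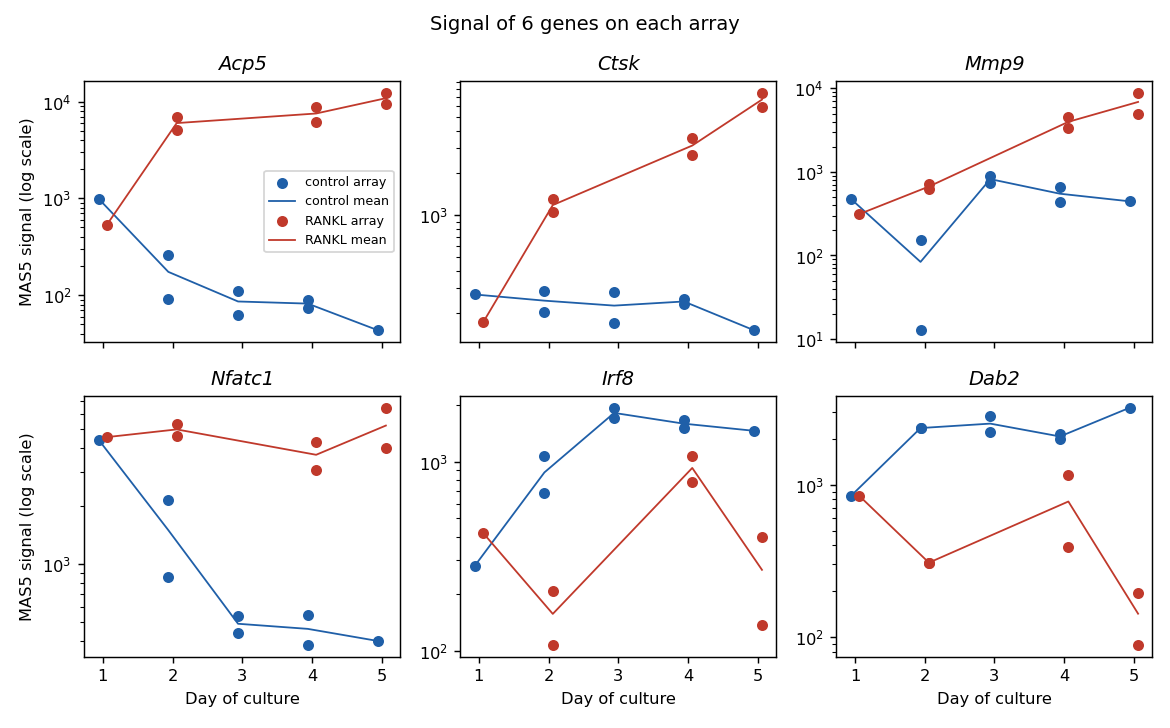
MAS5 signal (log axis) of Acp5, Ctsk, Mmp9, Nfatc1, Irf8 and Dab2 against day of culture, with 1 point for each array and lines through group means, blue for control and red for RANKL. At day 1, Acp5 was 992 without RANKL and 535 with it, while its RANKL group means from day 2 on lie between 5990 and 10827.

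By gene list, 7 of 16 osteoclast resorption genes rose with RANKL and 0 fell (10 rose when adjusted over the list alone), and the list shifted upward (adjusted p = 7.03e-16). Of 15 osteoclast transcription factors, Nfatc1, Myc (1.67 ± 0.31), Bhlhe40 (0.91 ± 0.14) and Fos rose (8 rose and 1 fell when adjusted over the list alone; adjusted p = 7.27e-08). These were the only 2 of 13 list shifts that held with an estimated correlation (adjusted p = 0.0126 for each). Of 27 interferon-response genes, 8 fell, among them Usp18, Ifi47 and Isg20, and 0 rose (19 fell when adjusted over the list alone). That list shifted downward (adjusted p = 1.17e-19; adjusted p = 0.0507 with an estimated correlation). Macrophage markers also shifted downward (adjusted p = 3.91e-06; adjusted p = 0.0843 with an estimated correlation), and 6 of 26 fell, among them Fcgr1, the complement receptor gene C3ar1 (-1.43 ± 0.23) and the integrin gene Itgam (-1.08 ± 0.19).

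Smaller shifts were spread over energy and stress genes. Of 48 oxidative phosphorylation genes, 45 had positive changes, with a median of 0.22 and 0 past the threshold (adjusted p = 2.17e-08; adjusted p = 0.279 with an estimated correlation). TCA cycle genes (median 0.20, 18 of 19 positive; adjusted p = 0.0507 with an estimated correlation) and V-ATPase genes (median 0.38; adjusted p = 0.0777 with an estimated correlation) shifted the same way. Of 15 V-ATPase genes Atp6v0e rose by 0.57 ± 0.11 (lost in 14 of 25 alternatives), and 9 rose when adjusted over the list alone. RANK and NF-kB signalling genes shifted upward (1 of 22 rose, Nfkb2 by 0.62 ± 0.10; adjusted p = 0.339 with an estimated correlation). Downward shifts were those of hypoxia response (median -0.31, 0 of 18 past the threshold, adjusted p = 0.0507 with an estimated correlation), unfolded-protein and integrated stress response (-0.22, 0 of 22, 0.279), cyclin-dependent kinase inhibitors (-0.14, 0 of 14, 0.152), negative regulators of osteoclast formation (-0.19, 1 of 14, 0.14) and inflammatory mediators (-0.22, 0.339), each with the adjusted p from the estimated correlation last. The 2 inflammatory mediators of 36 that passed the threshold went the other way: the chemokine receptor gene Ccr1 rose by 1.62 ± 0.15 and Plau, urokinase, by 1.20 ± 0.20 (0.31 for days 2 and 4 only; lost in 3 of 25 alternatives, and on 2 of 6 RANKL arrays of days 2, 4 and 5 it was below the 5 control arrays of those days).

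The remaining lists did not pass. Adjusted p was 0.0517 for lysosome (Ctsc fell by 1.16 ± 0.13 and Ctsl by 0.55 ± 0.11, the Ctsl call being lost in 15 of 25 alternatives), 0.0932 for ribosomal proteins, 0.107 for cell cycle, 0.139 for glycolysis and for oxidative stress response, 0.365 for dendritic cell markers, 0.56 for cell fusion and 0.602 for iron uptake and haem. It was 0.988 for podosome and cytoskeleton (Actn1 rose by 0.59 ± 0.09), reference genes and sterol biosynthesis. Markers of stromal, T, B, neutrophil and erythroid cells did not shift in any of 40 list tests (lowest adjusted p = 0.116), and 0 of their 55 members passed in any of the 8 comparisons.

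The count of 136 was 64 with the beta-actin 3' to 5' ratio as a covariate, a fit chosen after the values were seen, and 218 in the upper 50% of probe sets. The count also moved with single arrays. It was 11 without control day 5 replicate 1, when day 5 leaves the mean, 427 without either day 1 array, 297 without RANKL day 5 replicate 1, 89 without RANKL day 2 replicate 2, 80 without control day 2 replicate 2, and 90 or 84 without control day 4 replicate 1 or 2. Acp5 and Ctsk passed in all 25 alternatives. Of the 20 genes named for a large change with 1 direction on all 4 days, Nfatc1 and Ank passed in every alternative and 18 were lost without control day 5 replicate 1, Mst1r in 15 of 24 alternatives, Isg15 in 13 of 25 and Isg20 in 9 of 24; without the day 1 pair, chosen after the values were seen, 426 probe sets passed, 133 of them among the 136.

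At day 1 no gene passed the threshold with RANKL. The difference was -0.85 ± 0.51 for Acp5, -0.58 ± 0.36 for Ctsk, -0.56 ± 0.73 for Mmp9 and 0.04 ± 0.52 for Nfatc1. Nfatc1 signals were 4410 without and 4548 with RANKL, while control cells at days 3 to 5 had means from 399 to 490. The comparison sets 1 array against 1, and limma gave 0 of 12422 probe sets (728 at an unadjusted p under 0.05, smallest adjusted p = 0.275). Of the lists, lysosome genes shifted upward (median 0.22, 21 of 29 positive, 0 past the threshold, adjusted p = 0.0211; adjusted p = 0.859 with an estimated correlation). On simulated data this comparison recovered 13% of changes of log2 1 and 75% of those of log2 2.

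At day 2 Acp5 and Ctsk were higher with RANKL. Acp5 rose by 4.98 ± 0.36, from a mean signal of 174 ± 118 to 5990 ± 1307 (SD, n = 2), and Ctsk rose by 2.14 ± 0.26 (4.40-fold). Other large rises were those of Mmp9 (2.93 ± 0.51), Mycl, a relative of Myc (2.66 ± 0.54), Vegfc, a lymphatic growth factor (2.64 ± 0.35), and Gstt1, a glutathione transferase (2.35 ± 0.40). The largest falls were those of the endocytic adaptor gene Dab2 (-2.80 ± 0.40, 6.99-fold lower), Evl (-2.47 ± 0.38), Dusp6, a phosphatase of ERK kinases (-2.43 ± 0.45), Pea15a (-2.41 ± 0.36) and Rin2 (-2.39 ± 0.35). Irf8 fell by 2.29 ± 0.39 and Nfatc1 rose by 1.85 ± 0.37 (adjusted p = 0.0461); these calls were lost in 7 and 13 of 21 alternatives.

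At this day, 106 probe sets passed, 39 higher and 67 lower. Of 26 macrophage markers 5 fell, among them C3ar1 (-2.14) and Itgam (-1.87), and of 27 interferon-response genes 5 fell, among them Ifit1 (-2.18) and Ifi47 (-2.13). Among the day 2 genes, the calls lost in many alternatives were those of Mycl (14 of 20), Ifi47 (12 of 20, -3.12 to -1.35), Dusp6 (10 of 21) and C3ar1 (9 of 21). Both lists shifted downward, with adjusted p = 0.0683 with an estimated correlation. Resorption genes (3 of 16 rose) and osteoclast transcription factors (1 of 15 rose) shifted upward, with adjusted p = 0.0683 each with an estimated correlation. Of 22 RANK and NF-kB genes, Nfkb2 (1.37 ± 0.18) and Bcl3 (1.15 ± 0.16) rose, and the list shifted upward (adjusted p = 0.229 with an estimated correlation). Sterol biosynthesis shifted downward, with 15 of 16 members negative and a median of -0.48 (adjusted p = 0.399 with an estimated correlation). In all, 14 lists shifted, 7 in each direction, and 0 held with an estimated correlation. The count was 28 and 2 without control day 2 replicate 1 and 2, 5 and 3 without RANKL day 2 replicate 1 and 2, and 55 without either control day 4 array; 68 passed with no intensity trend. Acp5 passed in every alternative, and the other 9 of the 10 genes with the largest changes were lost without RANKL day 2 replicate 1.

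At day 4, when the labels call RANKL cells multi-nuclear, Acp5 was higher by 6.03 ± 0.36 (5.37 to 6.49 over the alternatives, since its control signals are dim and the value depends on the pseudocount), Ctsk by 3.53 ± 0.26 (11.5-fold), Ank by 2.94 ± 0.19, Nfatc1 by 2.91 ± 0.37 and Ccr1 by 2.62 ± 0.25. The 3 genes that fell were Ppfia4 (-1.93 ± 0.31), Rnase4 (-1.89 ± 0.32) and the lysosomal protease gene Ctsc (-1.75 ± 0.23, another of its probe sets having the opposite sign). The Rnase4 call was lost in 14 of 20 alternatives (-3.26 to -1.10), that of Ppfia4 in 5 of 20 (-2.65 to -1.25) and that of Ctsc in 3 of 21. The difference of 2.80 ± 0.51 for Mmp9 did not pass (adjusted p = 0.0573). In all, 33 probe sets passed, 27 higher and 6 lower, and the balance of rises and falls was nearer even without RANKL day 4 replicate 1. Resorption genes (4 of 16 rose, adjusted p = 0.013 with an estimated correlation) and osteoclast transcription factors (1 of 15, adjusted p = 0.0159 with an estimated correlation) shifted upward. V-ATPase genes also shifted upward, with 0 of 15 past the threshold and 8 when adjusted over the list alone (adjusted p = 0.179 with an estimated correlation). The interferon-response list shifted downward with 0 of 27 past the threshold and 5 lower when adjusted over the list alone (adjusted p = 0.299 with an estimated correlation), as did cell cycle genes (median -0.35, 38 of 47 negative, adjusted p = 0.488 with an estimated correlation). The count was 10 and 9 without control day 4 replicate 1 and 2, 54 without RANKL day 4 replicate 1 and 9 without RANKL day 4 replicate 2. Acp5, Ctsk, Ank and Ccr1 passed in every alternative.

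At day 5 Acp5 was higher by 7.15 ± 0.44 (6.24 to 7.91 over the alternatives, against a dim control signal of 43.5) and Ctsk by 5.19 ± 0.31 (36.6-fold), with Ctsk signals of 6698 ± 1107 (SD, n = 2) against 151 on the 1 control array. Mmp9 rose by 3.80 ± 0.63, Nfatc1 by 3.57 ± 0.45 and the mitochondrial gene Chchd10 by 3.26 ± 0.31. Dab2 fell by 4.27 ± 0.49, and Lgals9, galectin 9 (-3.63 ± 0.51), Selenbp1 (-3.22 ± 0.56), Pmp22 (-3.14 ± 0.64, its other probe set having the opposite sign) and the semaphorin receptor gene Nrp1 (-3.04 ± 0.51) also fell. Irf8 was lower by 2.46 ± 0.48, and it rose with culture time in control cells. Of the 10 genes with the largest rises and falls at day 5, 6 passed in every alternative, Pmp22 was lost in 13 of 20 and 3 were lost in 1 or 2; the Irf8 call was lost in 9 of 20.

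In all, 114 probe sets passed at day 5, 64 higher and 50 lower, around a median over all probe sets of 0.11 (0.02 after quantile normalization). The balance of rises and falls turned in other settings: it was 68 to 78 after quantile normalization, 71 to 75 with a pseudocount of 100 and 143 to 212 without RANKL day 5 replicate 1. Resorption genes (7 of 16 rose, among them Itgav by 3.24 ± 0.28) and osteoclast transcription factors (3 of 15: Nfatc1, Prdm1 by 2.05 ± 0.39, lost in 10 of 19 alternatives, and Bhlhe40 by 1.78 ± 0.29) shifted upward, with adjusted p = 0.0451 and adjusted p = 0.0465 with an estimated correlation. Of 36 inflammatory mediators 3 fell, among them the chemokine gene Ccl7 (-2.89 ± 0.52), and 1 rose. Of 26 macrophage markers 3 fell, among them Fcgr2b (-2.73 ± 0.30) and C3ar1 (-2.70 ± 0.49, lost in 8 of 20 alternatives). Both lists shifted downward (adjusted p = 0.0875 each with an estimated correlation), as did interferon-response genes (2 of 27 fell, adjusted p = 0.1 with an estimated correlation). Ccl7 and Fcgr2b rose with culture time in control cells. The glycolysis list shifted downward with 0 of 16 past the threshold (median -0.50, adjusted p = 0.121 with an estimated correlation), while sterol biosynthesis shifted upward with 0 of 16 (median 0.56, adjusted p = 0.626 with an estimated correlation). Of 15 lists that shifted, 2 held with an estimated correlation. The count was 355 without RANKL day 5 replicate 1, 52 without RANKL day 5 replicate 2, 63 and 62 without control day 2 replicate 1 and 2, and 66 without either control day 4 array; 244 passed in the upper 50% of probe sets and 64 with the replicate number as a block.

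**Figure D3:**
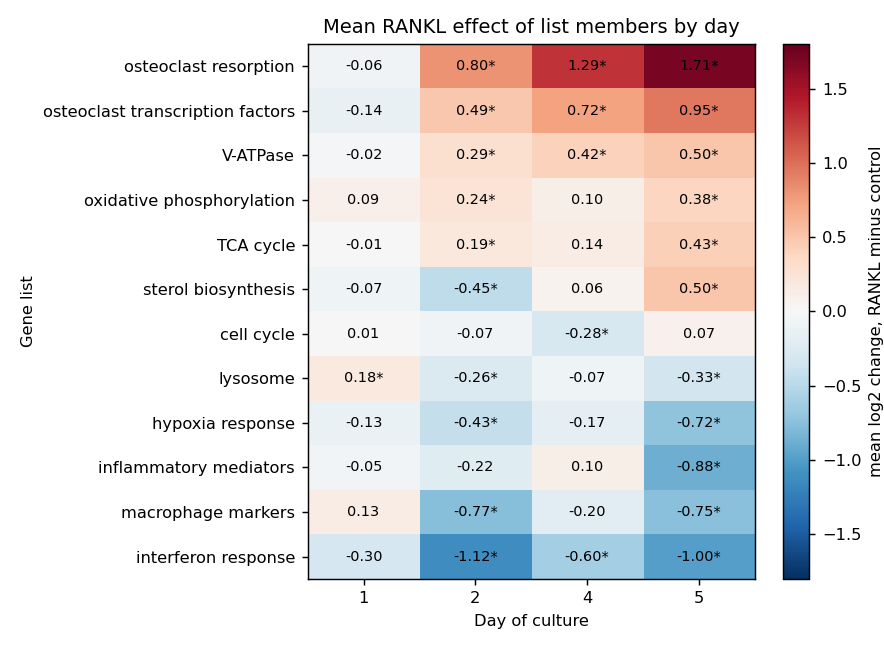
Mean log2 change, RANKL minus control, of the members of 12 gene lists at each day, with a star where the list test had an adjusted p under 0.05 at the preset correlation. The resorption list goes from -0.06 at day 1 to 1.71 at day 5, and the interferon-response list is lowest at day 2 (-1.12).

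Genes called at different days overlapped. Of the probe sets called at days 2 and 5, 15 higher and 20 lower ones were shared, where chance gives 0.20 and 0.27 if calls are independent. They are not fully independent, since 1 fit gives a probe set the same estimate of spread for every day. Days 2 and 4 shared 9 and 4, days 4 and 5 shared 14 and 2, and no probe set was called in opposite directions at these days. The same sign at day 1 was found for 31.1% of the 106 probe sets called at day 2, 66.7% of the 33 called at day 4 and 29.8% of the 114 called at day 5.

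The late minus early RANKL effect asks which responses to RANKL differ between the multi-nuclear and the mononuclear stage, with culture time taken out by the controls. The effect was larger late for Acp5 (4.53 ± 0.42, adjusted p = 0.00177), Ctsk (3.58 ± 0.30, adjusted p = 0.00108), Itgav (2.29 ± 0.27, adjusted p = 0.01), Ank (1.99 ± 0.22, adjusted p = 0.00656) and the transcription factor gene Egr2 (1.79 ± 0.26, adjusted p = 0.0453). These were the 5 probe sets called, all higher (998 at an unadjusted p under 0.05; after quantile normalization 4 higher and 1 lower). Of these genes Ank passed in all 23 alternatives, Acp5, Ctsk and Itgav were lost in 4 each and Egr2 in 17. Without either day 1 array the values were 1.61 for Acp5 and 2.22 for Ctsk, and for day 4 minus day 2 alone 1.05 and 1.39; that of Itgav was 1.52 without control day 5 replicate 1. Nfatc1 (2.29 ± 0.43) and Mmp9 (2.11 ± 0.60) did not pass. The resorption list shifted upward (3 of 16 rose; adjusted p = 0.0431 with an estimated correlation). The other 8 list shifts did not hold with an estimated correlation (adjusted p = 0.0872 to 0.799). Among them, transcription factors, V-ATPase and sterol biosynthesis were upward and cell cycle, glycolysis, inflammatory mediators, iron uptake and haem, and lysosome downward, with 0 members past the threshold. The early mean includes the day 1 pair; without that pair, or without either day 1 array, 2 passed. The count was 1 for day 4 minus day 2 alone (Ank), 3 without control day 2 replicate 1 or with no intensity trend, 12 in the upper 50% of probe sets, and 21 without RANKL day 5 replicate 1, 9 higher and 12 lower.

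Culture time in RANKL cells compares multi-nuclear with mononuclear cells directly. Mmp9 rose by 3.38 ± 0.41 (10.4-fold), Ctsk by 3.21 ± 0.20 (1.93 without the RANKL day 1 array), the chemokine gene Cxcl2 by 3.47 ± 0.91, Cox6a2 by 2.74 ± 0.66 and the sialyltransferase gene St6gal1 by 2.50 ± 0.33. The largest falls were those of Actb (-2.08 ± 0.29), Id1, an inhibitor of basic helix-loop-helix factors (-1.98 ± 0.34), Dctpp1 (-1.96 ± 0.25), Mybl2, a cell cycle transcription factor (-1.85 ± 0.22), and Dtymk, thymidylate kinase (-1.71 ± 0.21). The Actb value rests on 1 probe set, 101578_f_at; the manufacturer's beta-actin control at the 3' end had signals of 19510 to 31592 at days 1 and 2 and 15529 to 25465 at days 4 and 5. Acp5 (2.28 ± 0.29) and Tnf (2.13 ± 0.44) rose, but the Acp5 rise rests on the RANKL day 1 array (0.59 without it; lost in 2 of 23 alternatives), while the difference of -0.15 ± 0.29 for Nfatc1 did not pass. The replicates of RANKL day 5 differed for Cxcl2 (2075 ± 2817, SD, n = 2) and Cox6a2 (397 ± 526).

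In RANKL cells 1839 probe sets passed, 1116 higher and 723 lower (863 and 857 after quantile normalization, so the excess of rises depends on the scaling). Of 47 cell cycle genes 26 fell and 0 rose, with Aurka (-1.70), Pttg1 (-1.66), Birc5 (-1.62) and Cdc20 (-1.59) lowest. Of 16 resorption genes 10 rose, of 15 V-ATPase genes 7 rose, among them Atp6ap2 (1.64) and Atp6v1d (1.63), and of 29 lysosome genes 6 rose, Lamp2 most (1.79). Of 18 hypoxia-response genes 8 rose and 1 fell, of 36 inflammatory mediators 7 rose and 2 fell, of 26 macrophage markers 5 rose, among them Itgam (2.40) and Ptprc (2.03), and of 15 osteoclast transcription factors 4 rose. Of 48 oxidative phosphorylation genes 9 fell and 1 rose, of 27 interferon-response genes 4 fell, among them the chemokine gene Cxcl10 (-1.37), and of 17 oxidative stress genes 2 fell. These 11 lists shifted in the direction of most of their called members, and 0 held with an estimated correlation (adjusted p = 0.279 to 0.486). The count was 1146 without RANKL day 2 replicate 2 and 1086 with the beta-actin ratio as a covariate.

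Culture time in control cells asks what changes without RANKL over the same days. The largest rises include genes of inflammation, and Nfatc1 and Acp5 fell. The chemokine gene Cxcl2 rose by 4.57 ± 0.99, while another, Cxcl10, fell by 1.91 ± 0.27; Cox6a2 rose by 4.31 ± 0.72, Nfkbiz, a regulator of NF-kB targets, by 3.92 ± 0.67, the acute-phase gene Saa3 by 3.68 ± 0.50 and Acod1, which makes itaconate, by 3.20 ± 0.48. Nfatc1 fell by 2.44 ± 0.32 (-2.82 to -0.81 over the alternatives, where -0.81 is the slope per day of the linear trend and not a late minus early change). Falls were also those of Acp5 by 2.25 ± 0.31, Id2 by 2.73 ± 0.41, Fbxo15 by 2.31 ± 0.24 and Actb by 2.61 ± 0.32. For Actb, the other probe set had the opposite sign, and the manufacturer's control at the 3' end had signals of 20379 to 24144 at days 1 and 2 and 17120 to 21726 at days 4 and 5. The Acp5 fall rests on the control day 1 array: it was -1.02 without that array and -0.73 for day 4 minus day 2 alone (adjusted p = 0.105 and 0.332, from 0.000356 over the alternatives), and the call was lost in 4 of 25. Irf8 (1.56 ± 0.34) and Tnf (2.29 ± 0.48) rose and Fos fell by 0.72 ± 0.21 (its other probe set having the opposite sign; lost in 18 of 25 alternatives).

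In control cells 1348 probe sets passed, 743 higher and 605 lower. Of 29 lysosome genes 10 rose, among them Lamp2 (1.54) and Hexa (1.27, its other probe set having the opposite sign). Of 36 inflammatory mediators 7 rose and 1 fell, with Csf3 (2.98) and Ccl7 (2.50) among the rises, and of 26 macrophage markers 8 rose, Fcgr2b most (2.78). Of 47 cell cycle genes 16 fell and 1 rose, with Cdc6 (-1.49) and Aurka (-1.46) lowest. Of 16 sterol biosynthesis genes 7 fell, of 27 interferon-response genes 5 fell, of 48 oxidative phosphorylation genes 5 fell, of 18 hypoxia-response genes 4 rose, of 14 members of the cyclin-dependent kinase inhibitor list 3 rose, of 15 V-ATPase genes 2 rose, and of 17 oxidative stress genes 5 fell and 2 rose. These 11 lists shifted in the direction of most of their called members, and 0 held with an estimated correlation (adjusted p = 0.189 to 0.486). The count was 700 without control day 1 replicate 1, 769 without control day 2 replicate 1, 759 without control day 4 replicate 2, 555 for day 4 minus day 2 alone, 528 for a linear trend and 169 with the beta-actin ratio as a covariate.

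The changes with culture time were shared between treatments. RANKL and control cells had 456 higher and 356 lower probe sets in common, and 3 in opposite directions. Chance gives 66.8 and 35.2 in common if calls are independent, which calls from 1 fit are not fully. Across all probe sets, which are not independent replicates, the changes correlated at r = 0.66. The difference between the treatments is tested by the late minus early RANKL effect, which called 5 (998 at an unadjusted p under 0.05). On simulated data that comparison recovered 15% of changes of log2 1, against 65% for culture time in RANKL cells and 57% in control cells. Few calls therefore do not show that the changes are equal. No batch or date is given in the labels, so a batch between days cannot be told apart from culture time.

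**Figure D4:**
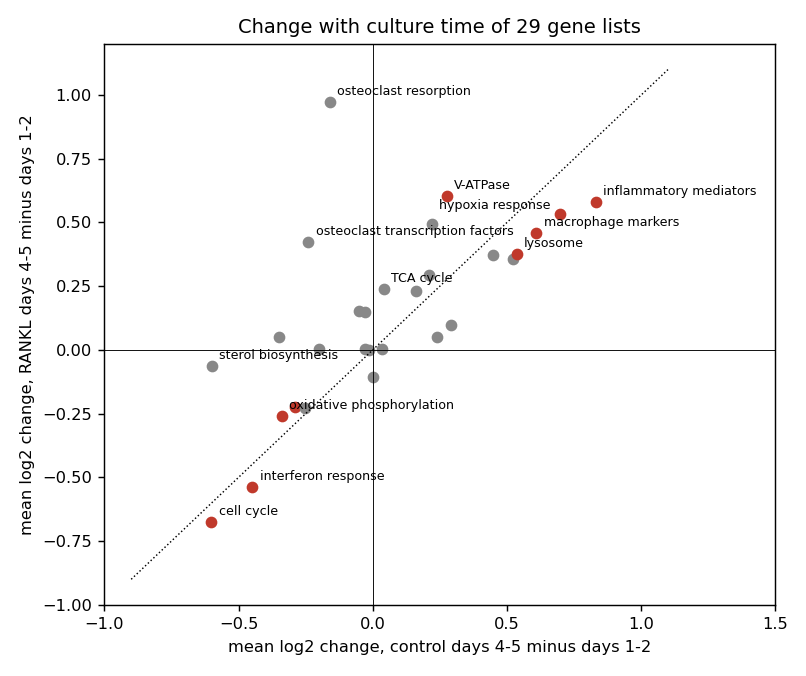
Mean log2 change with culture time of each of 29 gene lists in control cells (x axis) and RANKL cells (y axis), red where the list test passed in both at the preset correlation; the dotted line marks equal change. Cell cycle genes fall in both (-0.60 and -0.67), and resorption genes lie apart from the line at -0.16 in control cells and 0.97 in RANKL cells.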

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

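The tests of noise and of exchanged labels at day 1, the choice of probe sets for them, the test of a batch between days 2 and 3, and the difference of day 1 from the later days, were chosen after the results were seen.

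The RANKL effect differed between times in 2 tests of the difference itself. Late minus early, it differed by 4.53 for Acp5, 3.58 for Ctsk, 2.29 for Itgav, 1.99 for Ank and 1.79 for Egr2, but without either day 1 array by 1.61 for Acp5 and 2.22 for Ctsk. The mean list differences were 1.13 for osteoclast resorption, 0.66 for osteoclast transcription factors, 0.54 for sterol biosynthesis, 0.33 for V-ATPase, -0.074 for cell cycle, -0.16 for lysosome, -0.19 for iron uptake and haem, -0.20 for glycolysis and -0.25 for inflammatory mediators. Of these lists, resorption alone held with an estimated correlation. In 100 splits drawn from 700 possible ones, 4 gave 5 or more calls, the real one included, with 5 calls in the real split and 2213 in the highest other. With only 100 drawn, 4 of 100 is too near the bound of 5% for chance to be excluded here. The split with 2213 calls exchanged all 3 early and all 3 late control arrays, so it adds the culture-time changes of the 2 treatments instead of subtracting them; the other 2 splits, with 566 and 11 calls, placed 2 early RANKL arrays late and 2 late ones early, the latter with all control arrays exchanged. No group has 4 to 10 arrays, so single arrays were not tested against their group.

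The day 1 effect minus the mean effect of days 2, 4 and 5 differed for 6 probe sets, 2 higher and 4 lower, whereas most calls were higher without either RANKL day 5 array. The named genes were Acp5 (-6.91 ± 0.56, adjusted p = 0.000574), Ctsk (-4.20 ± 0.40, adjusted p = 0.00123), Ccr1 (-2.93 ± 0.39), Acaa1b (-2.13 ± 0.30) and Adcy2 (3.29 ± 0.43). Acp5 and Ctsk passed in all 19 alternatives run for this difference. The other 3 were lost in 5 (Ccr1), 14 (Acaa1b) and 8 (Adcy2) of them. The count of 6 was 3 without either control day 4 array or RANKL day 2 replicate 2, and 27 and 15 without RANKL day 5 replicate 1 and 2; it was 12 with a pseudocount of 1 (4 higher, 8 lower) and 12 in the upper 50% of probe sets (7 higher, 5 lower). The RANKL effect over days 2, 4 and 5 had 426 calls, and 237 without control day 2 replicate 2, 251 and 254 without control day 4 replicate 1 and 2, 155 without control day 5 replicate 1 and 267 without RANKL day 4 replicate 2.

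The first pattern is that RANKL-responsive probe sets had not moved at day 1. For the 426 probe sets called over days 2, 4 and 5, turned to their own direction, the median change was -0.11 at day 1, 0.79 at day 2, 0.68 at day 4 and 1.27 at day 5. For 123 probe sets called on the arrays of days 3 to 5 alone, neither day 1 nor day 2 took part in the choice. Their median was -0.03 at day 1 and 0.74 at day 2. The difference of 0.77 against at most 0.20 between replicates argues only against noise of the size seen between replicates. Replicates may not be separate cultures, so a single odd culture or array at day 1 stays open. Of all arrays, the RANKL day 1 array had the lowest median signal (103) and the smallest share of signals over 100 (50.4%). Its maximum signal (41016) and Gapdh 3' to 5' ratio (1.09) were the highest, while its beta-actin ratio (1.19) was not. Whether this array accounts for the pattern was not tested. Exchanging the 2 day 1 labels would only turn the day 1 median to 0.03, still 0.72 below day 2, so it does not account for the pattern, nor for Nfatc1, whose lower day 1 signal of 4410 is above the 2134 at most on the other control arrays; a single wrong label at day 1 was not tested and stays open. The 426 probe sets, turned the same way, lay on average 0.21 above their mean over all arrays on the control day 1 array. They lay 0.08 above it on the RANKL day 1 array. On the other control arrays they lay at -0.17 and -0.31 at day 2 and at -0.57 and -0.58 at day 3. At day 4 they lay at -0.57 and -0.57, and at day 5 at -0.74. Control values were highest at day 1, lower at day 2 and lower again from day 3 on. The control day 1 array was thus on the side of the RANKL arrays, though days 2, 4 and 5 took part in the choice. A slow response to RANKL is a biological explanation that the days of the design allow. It does not address the level of the control day 1 array, and it was not tested.

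The second pattern is the change with culture time, a step between days 2 and 3 in control cells, of whose calls 12% (162 of 1348) remained with the beta-actin ratio as a covariate, against 54.3% (998 of 1839) in RANKL cells. In control cells this met the bound for RNA quality as the cause, under 50%. The bound was written beforehand, but the fit was chosen after other results were seen. The median size, which was not part of the bound, went only from 0.97 (quartiles 0.77 to 1.29) to 0.96 (0.71 to 1.30). The median standard error rose from 0.205 to 0.294, so the calls ended through lost precision and RNA quality stays open there. In RANKL cells the median size went from 0.89 to 0.91. The slope of the ratio was estimated from replicate differences within groups alone. The value therefore argues against RNA quality as the whole cause only if the ratio acts between days as it does between replicates. A technical batch cannot be told apart from culture time, since 880 probe sets differed between control days 2 and 3 (49 and 317 without control day 2 replicate 1 and 2, 364 and 82 without control day 3 replicate 1 and 2) and limma called 0 between days 3 and 4 (574 at an unadjusted p under 0.05), and the labels give no dates. The medium was renewed on day 3 per the labels, and no biological explanation was tested.

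Other splits of the arrays were counted for the larger comparisons. For the RANKL effect over the 4 days, 1 of 100 splits drawn from 216 gave as many calls, the real one (136 calls, highest other 9). For culture time in RANKL cells, 1 of 35 splits did (1839 calls, highest other 672). Most other splits place arrays of different treatments or days in 1 group, which can widen the spread within groups and lower the calls. The labels also do not say whether replicates are separate cultures, so these splits cannot exclude chance between cultures. For culture time in control cells, the 10 splits are too few for a share under 0.05 (1348 calls, 1 split with as many, highest other 1).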

How the results depend on the processing

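The fits without the day 1 pair and with the beta-actin ratio as a covariate were chosen after the results were seen.

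The count for day 1 was 0 with limma in every alternative (728 at an unadjusted p under 0.05 in the reported fit). With pseudocounts of 1 and 100 and with quantile normalization, the counts of the 8 comparisons fixed beforehand stayed within 1.5 times the reported ones. Those of comparisons added later did not: with a pseudocount of 100, control day 4 minus day 3 went from 0 to 3 and control day 5 minus day 4 from 5 to 16, and with a pseudocount of 1 the difference of day 1 from later days went from 6 to 12. In the upper 50% of probe sets, where fewer are tested, the RANKL effect had 218 calls over the 4 days, 244 at day 5 and 12 late minus early. With no intensity trend it had 68 at day 2 and 3 late minus early, and with the replicate block 64 at day 5. Day 4 minus day 2 alone, which uses fewer arrays, gave 1 call late minus early and 555 in control cells, where a linear trend gave 528. Without the day 1 pair there were 426 calls over the days, 2 late minus early and 703 in control cells. With the beta-actin ratio there were 64 over the days (62 shared with the 136), 1086 in RANKL cells and 169 in control cells. Except where fewer probe sets or arrays were used, the cause was not tested.

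Without 1 array at a time, where a lone array left in a group is assumed to vary like the other groups, the counts ran from 11 to 427 over the days, 2 to 147 at day 2, 9 to 54 at day 4, 52 to 355 at day 5, 2 to 21 late minus early, 1146 to 1972 in RANKL cells and 700 to 1410 in control cells. The arrays that move each count are named beside it above.

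With an estimated correlation, the lists past the threshold went from 13 to 2 over the days, from 1 to 0 at day 1 and from 14 to 0 at day 2. They went from 5 to 2 at day 4, from 15 to 2 at day 5, from 9 to 1 late minus early, and from 11 to 0 in RANKL and in control cells. A higher correlation does not account for every loss. Over the days, negative regulators of osteoclast formation had an estimated correlation of -0.024, below the preset 0.01. Their unadjusted camera p still went from 0.013 to 0.0385. For interferon response the estimate was 0.237 and for oxidative phosphorylation 0.311. The day 1 list was also lost with quantile normalization and with the mean of a gene's probe sets (0 in each), and 4 lists passed late minus early after quantile normalization. The cause was not tested.

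For single genes, 280 results of 158 genes were followed. Of these, 10 fell short of the threshold with a pseudocount of 1, 13 with 100, 21 with quantile normalization, 34 with no intensity trend and 27 with the replicate block, and 0 changed direction in these. Losses were more common with the beta-actin ratio (91 of 193), for day 4 minus day 2 alone (34 of 77), for the linear trend (36 of 77), without the day 1 pair (42 of 198) and without 1 array at a time (597 of 4169). In control cells the culture-time change of Nfkb2 reversed, from -0.57 to 0.29 for day 4 minus day 2 alone and to 0.11 without the day 1 pair, and it ran from -0.67 to 0.11 without 1 array at a time (0.11 without control day 1 replicate 1). That of Hmox1 went from 0.93 to -0.01 (-0.013) for day 4 minus day 2 alone. The share of probe sets with signals over 100, between 50.4% and 56.2%, limits what dim genes can show.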

Other observations

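The comparisons of adjacent days and the tests of dim probe sets and of Irf8 were chosen after the results were seen.

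Between control days 4 and 5, the chemokine gene Ccl2 (2.84 ± 0.30, adjusted p = 0.00635), Adm, adrenomedullin (2.11 ± 0.26), and the phosphatase gene Acp1 (1.5 ± 0.22) rose, the 3 genes among 5 probe sets called. Those 5 calls were 0 without control day 4 replicate 2, 2 without control day 4 replicate 1, 13 without either RANKL day 5 array, and 3 without either array of day 1, control day 3, RANKL day 2 or RANKL day 4; they were 16 with a pseudocount of 100, 28 in the upper 50% of probe sets and 2 with the replicate block. Between RANKL days 1 and 2, Acp5 (3.39 ± 0.44), Ctsk (2.57 ± 0.31), Ccr1 (2.57 ± 0.31) and Acaa1b (2.40 ± 0.23) rose, the 4 genes among 5 probe sets called. Each of these comparisons sets 2 arrays against 1. In RANKL cells 1556 probe sets differed between days 2 and 4 and 79 between days 4 and 5. The comparisons of adjacent days in RANKL cells were not repeated under the alternatives. Between control days 1 and 2, limma called 0 (736 at an unadjusted p under 0.05). These genes were named after their values were seen.

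Of 22 genes of the unfolded-protein and integrated stress response, 4 rose with culture time in control cells and 12 had positive changes. Among the 4 were Ddit3 (2.85 ± 0.64), Trib3 (2.65 ± 0.63) and Atf3 (2.39 ± 0.56, another of its probe sets having the opposite sign), lost in 6, 6 and 7 of 25 alternatives. The list did not pass in control cells (adjusted p = 0.145) or in RANKL cells (adjusted p = 0.279), where Trib3 (2.21 ± 0.58) and Ddit3 (2.18 ± 0.59) rose.

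The third pattern is the lower interferon-response list with RANKL. A single control array is argued against as its cause, since the mean change of the list without any 1 array was at least 89.3% of that with all arrays. Dim probe sets are argued against too, since the 16 members with a mean signal over 100 changed by 131% of the mean of all 27 members. The fall of Irf8, a factor that drives interferon genes, is a hypothesis. Over days 1, 2, 4 and 5 the list means were -0.30, -1.12, -0.60 and -0.997 and the Irf8 changes 0.53, -2.29, -0.77 and -2.46. Their rank correlation was 0.8 (exact one-sided permutation p of 0.167, not under 0.05), so the order of the days leaves this hypothesis open. Against it, Irf8 rose by 1.56 with culture time in control cells while the list fell (mean -0.45, 5 of 27 fell, adjusted p = 0.00601; adjusted p = 0.486 with an estimated correlation), and the list's own shift with RANKL had an adjusted p of 0.0507 with an estimated correlation.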
